A study of Rattus norvegicus with 18 samples.

How the data were processed

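The deposited files held gene counts in 3 columns per library (unstranded and 1 for each strand), which per the submitters' processing notes came from bcl2fastq, Trimmomatic 0.38 and alignment to rn6 with STAR 2.6.1 before deposition. Libraries were made from total RNA depleted of ribosomal RNA with a directional kit and sequenced as paired reads. The strand that took nearly all of the counts (column 4) was used, and the other strand held 1.70 to 2.85% of them. All 28695 rows of the 18 files shared the same symbols.

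Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with edgeR's default filter (minimum count 10) by group, which left 11503, and libraries were scaled by TMM. A model with 1 mean per group was fitted to all 18 libraries (12 residual degrees of freedom) with robust quasi-likelihood dispersions, and 9 comparisons were tested, each with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 16.1%. Principal components used log2 CPM with a prior count of 2. Where a gene had 0 counts in a group, the fold is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% interval. Such bounds and intervals cover counting error only. Log2 fold changes from a refit, such as one with a library left out, are fitted values without a bound. Where a group then has 0 or few counts, their size is not exact.

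The comparisons, gene lists, rules for naming genes and all but 3 of the alternative settings were chosen before the data were examined. Genes and markers in the closing sections were chosen as stated there. The 28 lists of 577 genes, 554 of them in the files, were written from background knowledge. Those with at least 4 tested members (27 lists) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for each list and with fry. The lists not called in any comparison were primitive endoderm factors, anterior visceral endoderm, V-ATPase, BMP SMAD targets, LIF STAT3 targets, trophoblast markers, and blood and immune markers. The list of mesoderm and streak markers had 2 tested members and was not tested.

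Genes were named by rule. For each of the 6 main comparisons these were the 5 highest and the 5 lowest log2 fold changes among genes that passed, with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups, passing over placeholder symbols. For at most 5 called lists by p, the 3 members with the smallest adjusted p in the direction of the list were added. A fixed set of 16 genes was added in every comparison, from which Afp, Ttr and Apoa1 had too few counts to be tested. In the 3 secondary comparisons (sorted against unsorted, CHIR99021 against BCS, serum vesicles against CHIR99021-vacuolated cells) the numbers were 3 and 3, and 2 members for each of 3 lists. Other list members are named as examples beside the count of their list. Some list members that the rule names are not reported here.

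The code was tested on simulated data. In a simulated comparison of CHIR99021-vacuolated with normal cells over 11503 genes, with 50 genes changed at each fold, the test called 40% of those changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4- or 8-fold. Of 11278 unchanged genes it called 9. The changed genes were drawn from those above about 8 CPM in normal cells, with a dispersion taken from the trend rather than from each gene. These shares need not hold for genes with fewer counts.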

Results

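RNA was sequenced from 18 cultures of rat pXEN cells, which the labels call rat XENP, a cell type known as extraembryonic endoderm precursor cells. The cells came from blastocysts of the WKY strain and were labelled female. They fell into 6 groups of 3 libraries. Normal cells were grown in routine medium. Vacuolated cells were obtained in 3 ways, with the GSK3 inhibitor CHIR99021 at 0.5 µM, with the same inhibitor followed by a sort, and with 14% BCS, a supplement that the labels do not spell out. Vesicles were grown with CHIR99021 either with serum or without it. The growth protocol gives a CHIR99021 dose of 3 µM and murine LIF at 10 ng/ml for vesicles in N2B27 medium, which was taken to describe the serum-free ones, so the dose of the serum vesicles is not clear. Cells stood between passages 32 and 51. The labels say that samples were prepared independently but not whether each was a separate derivation. Every p of a gene below thus measures the spread between these samples. A camera p instead sets the genes of a list against the other genes tested. It rests on a preset or estimated correlation between genes and does not measure that spread alone.

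Each library held 4.05 M to 12.1 M strand-specific counts (median 7.09 M). A pair of unnamed clone-style genes took 37.6 to 61.1% of them, which left 1.92 M to 6.54 M counts for the other genes. That share was 37.6 to 43.6% in normal cells, 44.3 to 52.2% in unsorted CHIR99021-vacuolated and 45.2 to 49.3% in BCS-vacuolated cells. It was 45.8 to 53.4% in sorted vacuolated cells and 51.0 to 61.1% in the vesicles. What the pair encodes was not established, and mitochondrial RNA was not ruled out. The mitochondrially encoded shares given here leave the pair out, so they may miss part of the mitochondrial RNA. Mitochondrially encoded genes are here those with an Mt- symbol. They took 3.13 to 3.38% of the remaining counts in normal cells and 2.88 to 4.08% in unsorted CHIR99021-vacuolated cells. They took 3.29 to 4.32% in BCS-vacuolated cells, 6.76 to 8.91% in sorted vacuolated cells, 7.91 to 9.31% in serum vesicles and 7.11 to 9.43% in serum-free vesicles. Between 12779 and 15074 genes had at least 1 count per library. The files name genes by symbol without coordinates. Replicates of a group correlated at 0.937 to 0.986 across genes in log2 CPM (counts scaled for library size), where genes are not independent replicates. Values below are mean CPM ± SD with n = 3 libraries per group. Each gene comparison used edgeR's quasi-likelihood test on 11503 genes with Benjamini-Hochberg adjustment.

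The 18 libraries parted first into vesicles and all other cultures. The first principal component held 59.1% of the variance, with means of 81.4 ± 8.32 in serum vesicles, 80.7 ± 4.79 in serum-free vesicles and -56.0 ± 2.59 in normal cells. The vacuolated groups lay between, at -40.7 ± 3.34 with CHIR99021, -38.6 ± 2.28 with BCS and -26.8 ± 1.78 after the sort. The second component held 8.06% and separated serum vesicles (29.0 ± 15.5) from serum-free vesicles (-33.8 ± 6.28). On the third component (6.94%) BCS-vacuolated replicate 2 lay apart from its group, at -15.8 against -52.6 and -46.4 in replicates 1 and 3.

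**Figure D1:**
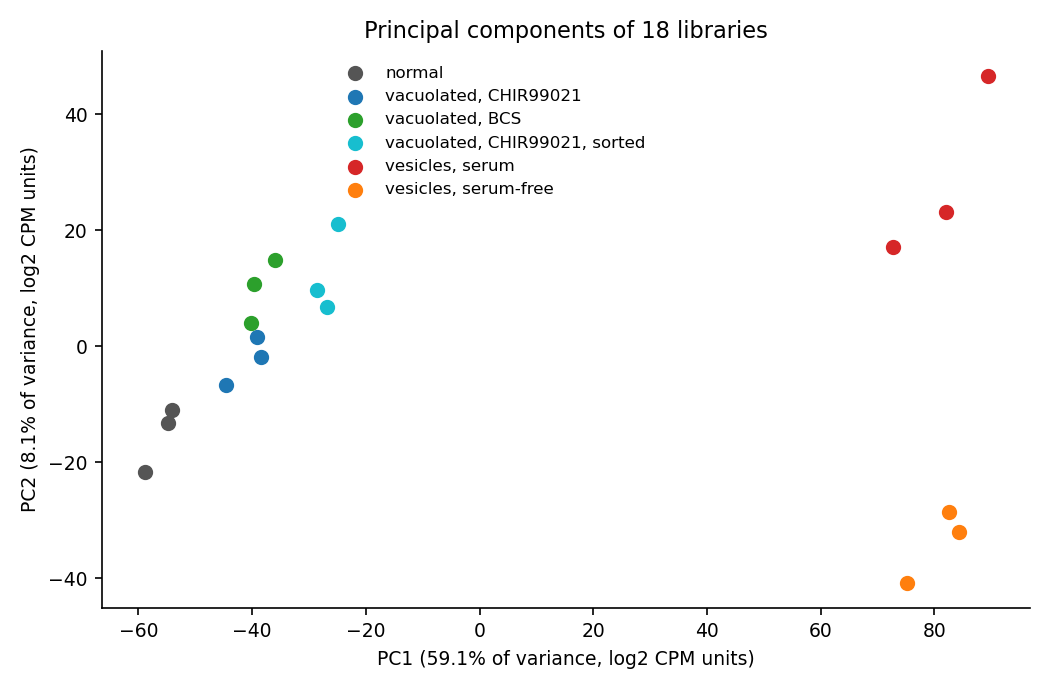
First and second principal components of log2 CPM over the 11503 genes tested, 1 point per library, coloured by group. The 6 vesicle libraries lie at the right, apart from the 12 others, and the groups with and without serum part on the second axis.

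**Figure D2:**
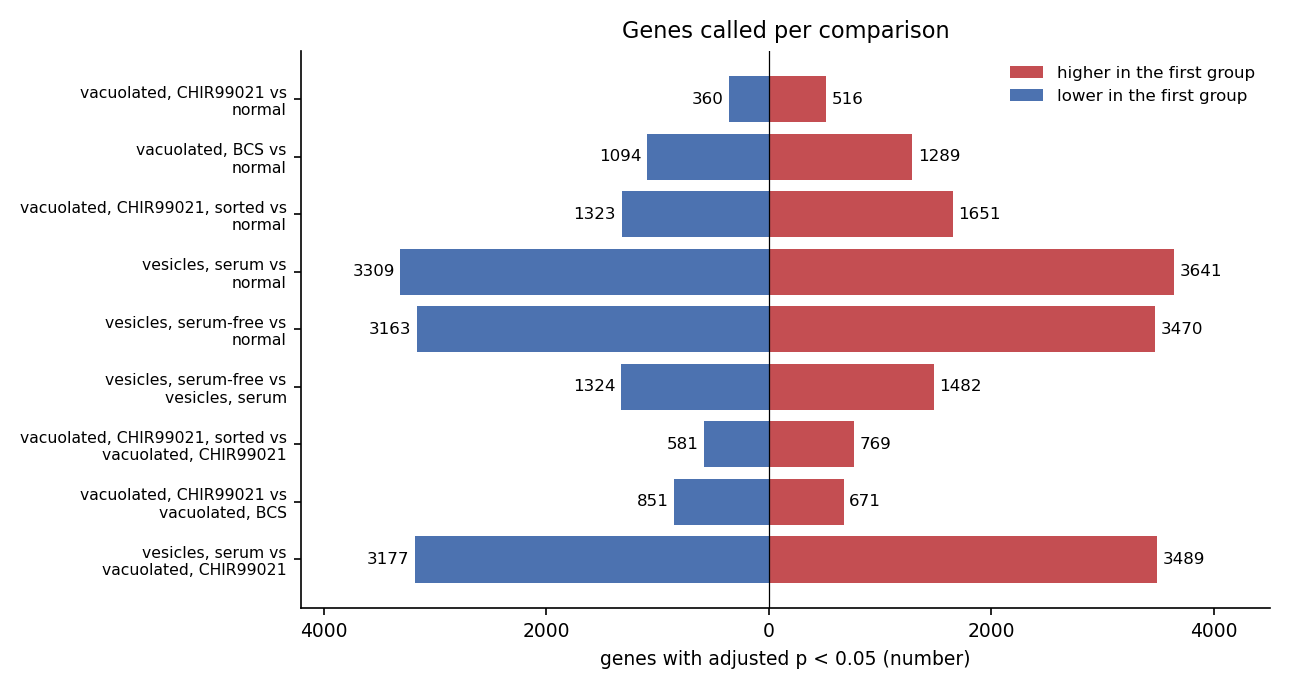
Number of genes higher (right) and lower (left) in the first group of each comparison at an adjusted p under 0.05 (edgeR quasi-likelihood test). The vesicle comparisons with normal cells hold 6950 and 6633 genes, and those of vacuolated with normal cells 876 to 2974.

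The first comparison asked how CHIR99021-vacuolated cells, before any sort, differed from normal cells. They carried more Gata2, a zinc-finger transcription factor (11.3 ± 1.78 against 0.472 ± 0.148 CPM, 23.8-fold, adjusted p = 1.46e-08), and more of the membrane proteases Mmp15 (14.7-fold) and Tmprss2 (8.63-fold). Ckmt1, a mitochondrial creatine kinase, rose 8.44-fold and RF00563, a non-coding RNA named by its Rfam family, 11.9-fold. Pou5f1, the pluripotency factor that rat extraembryonic endoderm precursors are known to keep, fell 2.95-fold (39.8 ± 8.05 against 118 ± 15.7 CPM, adjusted p = 1.26e-05). Fgf10, a fibroblast growth factor, fell 3.59-fold to 35.0 ± 3.19 CPM, and Cdkn1c, Sh3gl3, Gabarapl1 and Reep6 fell 3.47- to 3.67-fold. Among endoderm transcription factors, Gata6 fell 1.63-fold and Gata4 1.49-fold, while Sox17 had a log2 fold change of 0.22 (adjusted p = 0.462) and Sox7 of 0.79 (adjusted p = 0.104). Pdgfra (0.37, 0.182), Hnf4a (0.15, 0.780), Sparc (0.27, 0.188) and Thbd (-0.11, 0.683) also missed the threshold, and Lef1 had 0 counts in both groups.

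Some epithelial genes rose with vacuolation by CHIR99021. Of 31 members of the epithelial junction and polarity list, 8 were higher and 1 lower over all genes, and 12 and 2 adjusted over the list alone (camera adjusted p = 1.33e-05, adjusted p = 0.0634 with an estimated correlation). The tight-junction protein Cldn6 rose 4.58-fold (70.7 ± 1.44 against 15.4 ± 2.86 CPM), the keratins Krt18 and Krt8 rose 4.25- and 4.19-fold, and the adhesion molecule Cdh1 rose 3.08-fold. The mesenchymal filament gene Vim fell 2.27-fold. Hypoxia and glycolysis genes were higher for 10 of 27 members and lower for 0, with 13 and 2 adjusted over the list alone (adjusted p = 7.05e-06, adjusted p = 0.0634 with an estimated correlation). They included Ndrg1 (8.04-fold), the stress-induced mTOR inhibitor Ddit4 (3.09-fold) and the glycolytic enzyme Aldoa (2.21-fold).

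Wnt target genes appeared that normal cells did not show. The stem-cell receptor Lgr5 had 135 counts in CHIR99021-vacuolated cells and 0 in normal cells, at least 38.6-fold higher against a floor of 3 counts over the group, and the Wnt feedback gene Axin2 had 33 against 0, at least 9.45-fold higher. Tnfrsf19 rose 7.11-fold. These were the 3 of 13 list members that passed, also adjusted over the list alone (camera adjusted p = 0.0386, adjusted p = 0.169 with an estimated correlation). The call of the list ended without a low-count filter (adjusted p = 0.0698), after thinning to equal counts outside the 2 most abundant genes (0.0701) and with the 2 groups fitted alone (0.537). Cholesterol biosynthesis genes were lower for 4 of 25 members and higher for 2, with 6 and 2 adjusted over the list alone (adjusted p = 0.0386, adjusted p = 0.553 with an estimated correlation), and the sterol genes Stard4 and Msmo1 each fell 1.61-fold and Lss 1.71-fold. That list's call ended without normal replicate 1 (adjusted p = 0.0976), without normal replicate 2 (0.0582), without CHIR99021-vacuolated replicate 1 (0.108), after thinning (0.0701) and with those 2 groups alone (0.0956). ER chaperones were lower for 1 of 18 members and for 5 adjusted over the list alone (adjusted p = 0.0316, adjusted p = 0.499 with an estimated correlation and 0.0503 by fry). The member that passed, Sdf2l1, fell 1.87-fold, while Pdia6 (log2 fold change -0.50, adjusted p = 0.0529) and Dnajb11 (-0.45, 0.0535) did not pass.

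In all, 876 of 11503 genes differed, 516 higher and 360 lower, with 348 of them over 2-fold. The count was 504 without CHIR99021-vacuolated replicate 1, 527 without normal replicate 2 and 1856 with the 2 groups fitted alone. Sdf2l1 missed the threshold without normal replicate 2 (adjusted p = 0.113) or CHIR99021-vacuolated replicates 1 (0.101) or 3 (0.0546), and so did Gata4 without normal replicate 2 (0.117) or CHIR99021-vacuolated replicates 1 (0.0715) or 2 (0.0885) and Lss without CHIR99021-vacuolated replicate 1 (0.0578).

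Cells vacuolated with BCS carried more of many lysosomal transcripts than normal cells. Of 35 tested members of that list, 20 were higher and 0 lower, and 21 adjusted over the list alone (camera adjusted p = 2.25e-11, adjusted p = 0.0362 with an estimated correlation). The protease Ctsb rose 8.45-fold to 128 ± 8.58 CPM (adjusted p = 1.18e-12), the acid glucosidase Gaa 6.71-fold and Ctsa 2.18-fold. Grn, which encodes the lysosomal protein progranulin, rose 10.6-fold. The receptor Igf2r, which carries enzymes to lysosomes, rose 17.8-fold but spread widely (101 ± 75.8 against 5.59 ± 1.49 CPM), and the plasminogen activator Plat rose 14.9-fold and RF00563 10.4-fold.

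Epithelial and glycolytic genes were also higher in BCS-vacuolated cells. In the epithelial list, 15 of 31 members were higher and 0 lower, and 19 adjusted over the list alone (adjusted p = 1.90e-09, adjusted p = 0.0122 with an estimated correlation). Cldn6 rose 5.62-fold, Krt18 3.72-fold, Cdh1 3.51-fold and the tight-junction gene Ocln 2.86-fold. Among the hypoxia and glycolysis genes, 15 of 27 were higher and 1 lower, and 16 and 1 adjusted over the list alone (adjusted p = 1.90e-09, adjusted p = 0.0138 with an estimated correlation), led by Ndrg1 at 13.2-fold, Ddit4 at 3.95-fold and Aldoa at 3.86-fold. Basement membrane genes were higher for 9 of 14 members and lower for 1, over all genes and adjusted over the list alone (adjusted p = 5.50e-04, adjusted p = 0.220 with an estimated correlation). The type IV collagen gene Col4a2 reached 2695 ± 381 against 1131 ± 64.8 CPM, and Lama5 rose 3.07-fold and Lamb2 2.16-fold. Parietal endoderm genes were higher for 7 of 14 members and lower for 1, and 8 and 2 adjusted over the list alone (adjusted p = 5.50e-04, adjusted p = 0.107 with an estimated correlation), among them Sparc at 1.76-fold.

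Immediate early genes, the first genes that a stimulus induces, were higher in BCS-vacuolated cells for 8 of 15 members and lower for 0, and 9 adjusted over the list alone (adjusted p = 1.28e-05, adjusted p = 0.0922 with an estimated correlation). Dusp1 rose 3.76-fold, Cyr61 3.18-fold and Klf6 2.24-fold. Cholesterol genes were higher for 8 of 25 members and lower for 1 (adjusted p = 0.00140, adjusted p = 0.169 with an estimated correlation). Fatty acid synthesis genes were higher for 7 of 14 and lower for 1 (adjusted p = 5.50e-04, adjusted p = 0.133 with an estimated correlation). For both lists the counts adjusted over the list alone were identical. In the mesenchymal transition list, 5 of 12 members were higher and 1 lower, and 7 and 1 adjusted over the list alone (adjusted p = 0.00401, adjusted p = 0.0922 with an estimated correlation), although Vim itself fell 1.58-fold. Mitochondrially encoded genes were higher for 5 of 13 members and 6 adjusted over the list alone (adjusted p = 0.00401, adjusted p = 0.563 with an estimated correlation and 0.0849 by fry), beside a share of 3.29 to 4.32% against 3.13 to 3.38% of counts. Endocytosis genes were higher for 6 of 27 members and lower for 3, and 8 and 4 adjusted over the list alone (adjusted p = 0.0450, adjusted p = 0.365 with an estimated correlation). The endocytosis call ended without normal replicates 1 (adjusted p = 0.0620) or 3 (0.0597) or BCS-vacuolated replicate 2 (0.242), after thinning (0.0743), with passage as a covariate (0.0892) and in the blocked fit (0.0572).

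Pou5f1 fell 1.63-fold in BCS-vacuolated cells and the neuronal gene Stmn2 4.61-fold, with Pllp, Reep1, Ngfr and Slc43a2 3.01- to 3.82-fold lower. Sox7 rose 2.72-fold and Hnf4a, a factor of visceral endoderm, 1.62-fold. Gata6 had a log2 fold change of 0.07 (adjusted p = 0.760), Gata4 of -0.37 (0.0777) and Pdgfra of -0.43 (0.0604), Sox17 of 0.14 (0.566) and Thbd of 0.31 (0.0933). Axin2 had 6 counts against 0, at least 1.53-fold higher (adjusted p = 0.170). Its fitted log2 fold change, whose size is not exact against 0 counts, was 4.05. It was 4.71 without BCS-vacuolated replicate 2 and 3.15 without replicate 3. Lef1 had 0 counts in both groups. In all, 2383 genes differed, 1289 higher and 1094 lower, with 725 over 2-fold.

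That count was 1275 without BCS-vacuolated replicate 1 and 1530 without normal replicate 2. Without BCS-vacuolated replicate 2 the log2 fold changes of Stmn2, Pllp, Reep1 and Ngfr were -3.27, -2.76, -2.53 and -2.22, against -2.20, -1.93, -1.68 and -1.60 with it, and without replicate 1 that of Igf2r was 3.55 against 4.15. Igf2r and Stmn2 missed the threshold with the 2 groups fitted alone (adjusted p = 0.0554 and 0.0958). So did Hnf4a without normal replicates 1 (0.0743) or 3 (0.0871) or BCS-vacuolated replicates 1 (0.0504) or 3 (0.0852) and after thinning (0.139), Vim without normal replicate 1 (0.0672) or BCS-vacuolated replicate 3 (0.0534), and Pou5f1 without normal replicate 3 (0.0666).

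Sorted CHIR99021-vacuolated cells were also compared with normal cells. Gata2 rose 22.2-fold (10.6 ± 0.583 against 0.472 ± 0.148 CPM, adjusted p = 5.26e-09), Mmp15 17.1-fold, Ndrg1 15.2-fold and the activin antagonist Fst 12.7-fold. Pou5f1 fell 3.08-fold (38.2 ± 1.99 CPM), Tfec 4.49-fold, the BMP target Id3 3.81-fold, B3galnt1 3.68-fold, Slc43a2 3.49-fold and Cdkn1c 3.40-fold. Vim fell 2.08-fold and Thbd, a parietal endoderm marker, 1.43-fold. Gata4 fell 1.34-fold (adjusted p = 0.0398) and Sox7 rose 1.90-fold (adjusted p = 0.0188). The call of Gata4 ended without any 1 of the 6 libraries (adjusted p = 0.0507 to 0.175), and that of Sox7 without normal replicates 2 (0.103) or 3 (0.0540) or sorted replicate 2 (0.0867).

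Mitochondrially encoded genes with an Mt- symbol stood out in the sorted cells. Of 13 tested, 11 were higher and 0 lower, over all genes and adjusted over the list alone. The list had a camera adjusted p of 8.60e-11, and an adjusted p of 0.119 with an estimated correlation. Mt-cyb rose 2.74-fold (3500 ± 620 against 1276 ± 52.0 CPM) and Mt-atp6 3.08-fold. Mt-nd4 rose 12.3-fold from 60 counts in normal cells, far below the 22236 of Mt-cyb, so it was measured on few reads. Immediate early genes were higher for 8 of 15 members by either adjustment, including adjusted over the list alone, and lower for 0 (adjusted p = 5.22e-06, adjusted p = 0.119 with an estimated correlation). Jun rose 4.43-fold and Klf6 2.74-fold. Fosb had 728 counts against 1, a ratio of 418 (95% counting interval 74.8 to 16526). Its fitted log2 fold change was 8.25, and 10.37 without normal replicate 3, where normal cells had at most 1 count and the size is not exact. It was 6.91 on unstranded counts and 7.51 after thinning. The mitochondrially encoded share was 6.76 to 8.91% of the counts in these libraries against 3.13 to 3.38% in normal cells, and they held 4.48 M to 6.54 M counts outside the 2 dominating genes against 2.54 M to 3.32 M.

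Epithelial genes were higher in sorted cells for 16 of 31 members and lower for 1, and 18 and 1 adjusted over the list alone (adjusted p = 5.22e-06, adjusted p = 0.0671 with an estimated correlation), with Cldn6 at 5.81-fold, Cdh1 at 3.87-fold, Krt8 at 3.37-fold and Krt18 at 3.28-fold. Hypoxia and glycolysis genes were higher for 11 of 27 and lower for 0, and 12 adjusted over the list alone (adjusted p = 5.22e-06, adjusted p = 0.0781 with an estimated correlation), with Ddit4 at 5.03-fold and Aldoa at 4.15-fold. In the basement membrane list, 11 of 14 members were higher and 0 lower, and 12 and 1 adjusted over the list alone (adjusted p = 4.21e-05, adjusted p = 0.166 with an estimated correlation), among them Lama5 (3.66-fold), Lamb2 (2.12-fold) and Col4a2 (1.72-fold). Parietal endoderm genes were higher for 6 of 14 and lower for 3, with the same counts adjusted over the list alone (adjusted p = 0.0107, adjusted p = 0.184 with an estimated correlation). Lysosomal genes were higher for 11 of 35 and lower for 2, and 12 and 4 adjusted over the list alone (adjusted p = 0.0230, adjusted p = 0.534 with an estimated correlation). Integrated stress response genes were higher for 8 of 22 and lower for 1, and 9 and 1 adjusted over the list alone (adjusted p = 0.0231, adjusted p = 0.534 with an estimated correlation).

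Wnt targets were higher in sorted cells for 4 of 13 members by both counts, also adjusted over the list alone (adjusted p = 0.0283, adjusted p = 0.119 with an estimated correlation, 0.140 with the 2 groups alone). Lgr5 had 106 counts against 0, at least 20.3-fold higher, and Axin2 48 against 0, at least 9.18-fold higher. Aquaporin and fluid transport genes were higher for 4 of 15, again also adjusted over the list alone (adjusted p = 0.0302, adjusted p = 0.119 with an estimated correlation). That call ended without normal replicate 3 (adjusted p = 0.0557), without sorted replicate 2 (0.0537) and on unstranded counts (0.0565). Mesenchymal transition genes were higher for 6 of 12 and lower for 1 by either adjustment, including adjusted over the list alone (adjusted p = 0.0391, adjusted p = 0.169 with an estimated correlation, 0.0557 without normal replicate 3). Gata6 had a log2 fold change of 0.29 (adjusted p = 0.132), Sox17 of -0.05 (0.844), Hnf4a of 0.04 (0.919), Pdgfra of 0.15 (0.536) and Sparc of 0.15 (0.372), and Lef1 had 0 counts in both groups. In all, 2974 genes differed, 1651 higher and 1323 lower, with 905 over 2-fold. The count was 1982 without sorted replicate 2.

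Serum vesicles lost Pou5f1 almost wholly when compared with normal cells, from 118 ± 15.7 to 1.25 ± 0.482 CPM (88.3-fold lower, adjusted p = 3.34e-14). Fgf10 fell from 2200 to 6 counts (362-fold), Tfec 72.8-fold, Dnmt3l, a cofactor of DNA methylation, 69.7-fold and Stmn2 40.6-fold. Tmprss2 rose 296-fold (260 ± 20.7 CPM), Gata2 174-fold, Mmp15 149-fold and the cytoskeletal gene Add3 49.1-fold. Mir675 rose 55.3-fold, and as this microRNA lies within the H19 transcript its counts may include reads of H19. Gata6 fell 5.72-fold, Gata4 2.64-fold, Sox17 1.74-fold, Sparc 2.09-fold and Thbd 9.92-fold, while Hnf4a rose 4.91-fold (40.9 ± 5.93 CPM). Pdgfra (log2 fold change 0.31, adjusted p = 0.0994) and Sox7 (0.07, 0.857) missed the threshold.

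Epithelial genes rose in serum vesicles, with 25 of 31 members higher and 2 lower, also adjusted over the list alone (camera adjusted p = 5.29e-09, adjusted p = 0.0129 with an estimated correlation). Cdh1 rose 27.1-fold to 219 ± 37.0 CPM, Cldn6 11.8-fold and Ocln 5.59-fold, and Vim fell 25.3-fold. Aquaporin and fluid transport genes were higher for 11 of 15 members and lower for 2, likewise adjusted over the list alone (adjusted p = 2.14e-04, adjusted p = 0.0129 with an estimated correlation). Wnt targets were higher for 10 of 13 and lower for 3 by both counts, including adjusted over the list alone (adjusted p = 0.00133, adjusted p = 0.0353 with an estimated correlation). Lgr5 had 771 counts, Cdx2, a factor of intestine and trophectoderm, 457, Axin2 278 and Lef1 53, each against 0 in normal cells, at least 247-, 146-, 89.0- and 16.98-fold higher, and on unstranded counts the log2 fold change of Lef1 was 4.59. Proliferation genes were lower for 26 of 31 members and higher for 1, also adjusted over the list alone (adjusted p = 5.29e-09, adjusted p = 0.0493 with an estimated correlation), with the cyclin Ccne1 5.10-fold lower and the ribonucleotide reductase genes Rrm2 and Rrm1 3.83- and 2.65-fold lower.

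Lysosomal genes were higher in serum vesicles for 24 of 35 members and lower for 3, and 24 and 4 adjusted over the list alone (adjusted p = 2.14e-04, adjusted p = 0.222 with an estimated correlation). Ctsb rose 22.0-fold to 333 ± 48.5 CPM, Glb1 6.59-fold and Asah1 3.43-fold. ER chaperones were lower for 13 of 18 and higher for 2, and 14 and 2 adjusted over the list alone (adjusted p = 7.34e-05, adjusted p = 0.0939 with an estimated correlation), with Dnajb11 4.52-fold, Pdia4 4.03-fold and Hspa5, the main chaperone of the ER, 3.64-fold lower. Mitochondrially encoded genes were higher for 12 of 13, also adjusted over the list alone, beside a share of 7.91 to 9.31% of counts. Their camera adjusted p was 5.88e-05, and 0.355 with an estimated correlation. Mt-cyb rose 3.27-fold, Mt-co3 2.89-fold and Mt-nd4, on few reads, 11.1-fold. Immediate early genes were higher for 9 of 15 and lower for 1 by both counts, including adjusted over the list alone (adjusted p = 0.0312, adjusted p = 0.385 with an estimated correlation, 0.0509 without serum vesicle replicate 1). In all, 6950 genes differed, 3641 higher and 3309 lower, with 4031 over 2-fold. Some folds of genes near 0 in vesicles rested on single libraries. The log2 fold change of Fgf10 was -12.84 without serum vesicle replicate 2, a fitted value on at most 6 counts and not an exact size. It was -7.88 without replicate 1 (-8.50 with both). Without replicate 1 the log2 fold changes of Tfec and Dnmt3l were -6.84 and -7.04 (-6.19 and -6.12 with it).

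**Figure D3:**
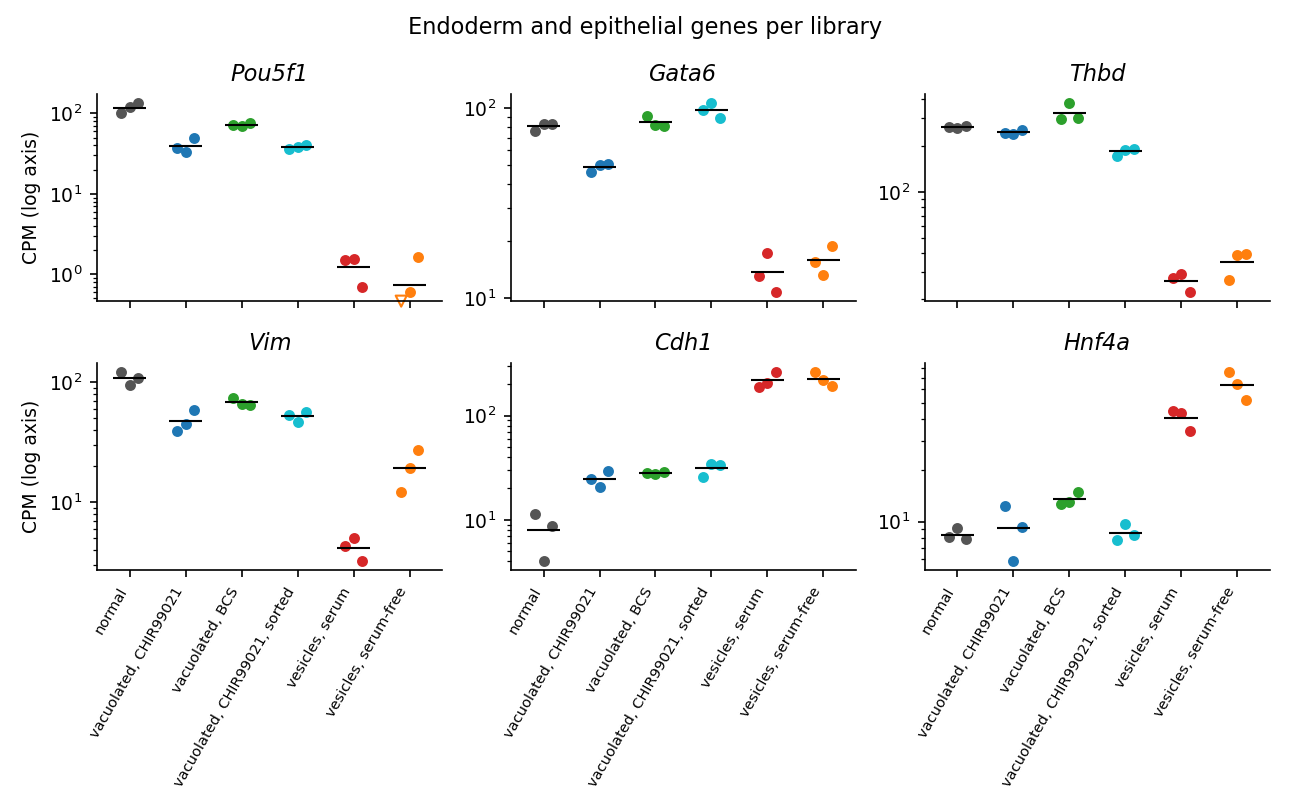
CPM on a log axis of 6 genes in each library, with 1 point per library and a black bar at the mean of 3, and an open triangle at the axis for the library with 0 counts of Pou5f1. Pou5f1, Gata6, Thbd and Vim are lowest in the vesicle groups, and Cdh1 and Hnf4a are highest there.

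Serum-free vesicles differed from normal cells in Pou5f1, Dnmt3l, Tmprss2, Mmp15, Gata2 and Mir675, as serum vesicles did. Pou5f1 fell 136-fold to 0.746 ± 0.824 CPM (adjusted p = 7.50e-15), Car12 87.8-fold, Dnmt3l 84.8-fold, Pdzd3 57.9-fold and the retinol receptor Stra6 50.03-fold. Tmprss2 rose 218-fold (191 ± 2.37 CPM), Mmp15 161-fold, Gata2 123-fold, the growth factor carrier Igfbp2 65.1-fold and Mir675 61.7-fold. Gata6 fell 5.04-fold, Gata4 2.20-fold, Thbd 7.504-fold and Sox17 1.32-fold, and Hnf4a rose 7.63-fold and Pdgfra 1.49-fold. Sparc had a log2 fold change of -0.25 (adjusted p = 0.0719) and Sox7 of 0.43 (0.230).

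Here 27 of 31 epithelial genes were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 8.46e-12, adjusted p = 0.00381 with an estimated correlation). Cdh1 rose 27.7-fold, Cldn6 13.2-fold and Ocln 7.98-fold, and Vim fell 5.49-fold. Aquaporin and fluid transport genes were higher for 10 of 15 and lower for 2, also adjusted over the list alone (adjusted p = 3.16e-04, adjusted p = 0.0141 with an estimated correlation). The sodium-proton exchanger Slc9a3 had 2508 counts against 0, at least 657-fold higher, the carbonic anhydrase Car2 rose 122-fold and the sodium pump subunit Atp1b1 4.43-fold. Wnt targets were higher for 10 of 13 and lower for 2 by both counts, including adjusted over the list alone (adjusted p = 0.00264, adjusted p = 0.0458 with an estimated correlation). Lgr5 had 978 counts, Cdx2 479, Axin2 108 and Lef1 21, each against 0, at least 256-, 125-, 28.3- and 5.50-fold higher, and on unstranded counts the log2 fold change of Lef1 was 3.17.

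Lysosomal genes were higher in serum-free vesicles for 23 of 35 members and lower for 4, also adjusted over the list alone (adjusted p = 3.95e-05, adjusted p = 0.171 with an estimated correlation), with Ctsb at 26.2-fold and Glb1 at 8.59-fold. Proliferation genes were lower for 24 of 31 and higher for 3, and 26 and 3 adjusted over the list alone (adjusted p = 9.50e-07, adjusted p = 0.114 with an estimated correlation), with Ccne1 7.41-fold, Bub1 2.69-fold and Tyms 2.42-fold lower. ER chaperones were lower for 11 of 18 and higher for 3 by both counts, including adjusted over the list alone (adjusted p = 0.00764, adjusted p = 0.207 with an estimated correlation). Mitochondrially encoded genes were higher for 12 of 13, also adjusted over the list alone (adjusted p = 8.50e-06, adjusted p = 0.246 with an estimated correlation), and Mt-co3 rose 3.74-fold, Mt-cyb 3.66-fold and Mt-nd4 10.9-fold, beside a share of 7.11 to 9.43% of counts.

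Calls of other lists in serum-free vesicles were less firm. Visceral endoderm genes were higher for 11 of 15 and lower for 2, also adjusted over the list alone. The camera call (adjusted p = 0.0407, adjusted p = 0.289 with an estimated correlation) ended without serum-free replicate 2 (adjusted p = 0.0692). In that library Afp and Apoa1 had 252 and 346 counts, but neither was among the 15 tested members. Pluripotency genes were lower for 7 of 11 and higher for 2, also adjusted over the list alone (adjusted p = 0.0407, adjusted p = 0.133 with an estimated correlation), which ended after thinning (0.0687) and with the 2 groups alone (0.0618). Mesenchymal transition genes were lower for 5 of 12 and higher for 1, also adjusted over the list alone (adjusted p = 0.0291, adjusted p = 0.159 with an estimated correlation). This ended without normal replicate 2 (0.0530), without serum-free replicate 3 (0.103), without a low-count filter (0.0591), after thinning (0.0687) and with the 2 groups alone (0.108). Immediate early genes were higher for 10 of 15 and lower for 2, also adjusted over the list alone (adjusted p = 0.0424, adjusted p = 0.324 with an estimated correlation), which ended without serum-free replicates 2 (0.0855) or 3 (0.0554) and with the 2 groups alone (0.102).

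In all, 6633 genes differed between serum-free vesicles and normal cells, 3470 higher and 3163 lower, with 3619 over 2-fold. Without serum-free replicate 3 the log2 fold changes of Pou5f1, Pdzd3 and Stra6 were -8.26, -6.90 and -6.86 (-7.09, -5.86 and -5.64 with it). Sox17 missed the threshold without normal replicates 2 (adjusted p = 0.189) or 3 (0.0545) or serum-free replicates 1 (0.0743) or 2 (0.122).

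**Figure D4:**
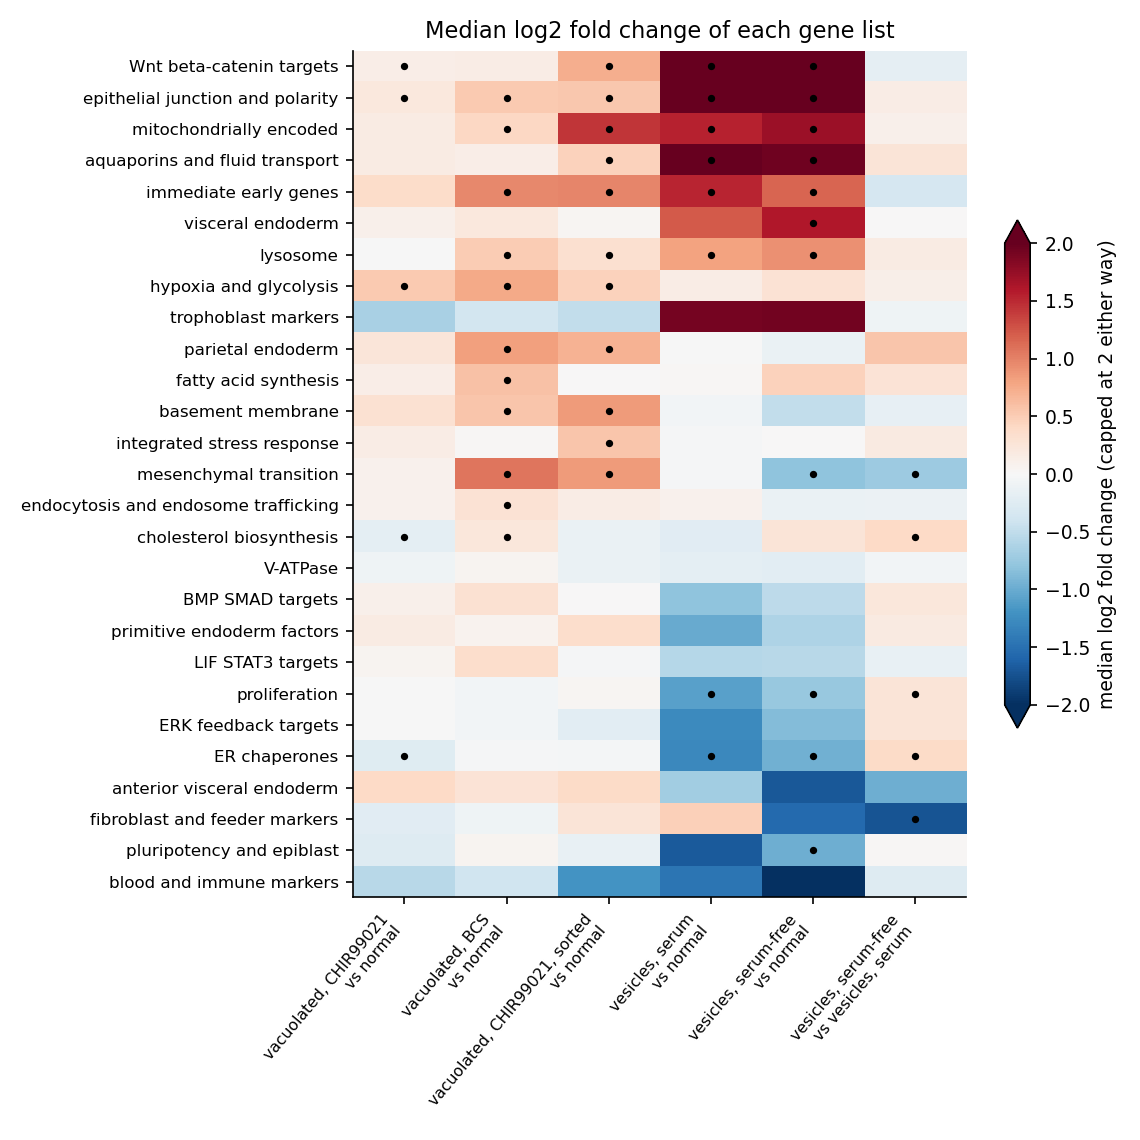
Median log2 fold change of the tested members of each of 27 gene lists (rows) in the 6 main comparisons (columns), with genes at 0 counts in a group placed at their lower bound and the colour capped at 2 either way. Dots mark a camera adjusted p under 0.05 with the preset correlation of 0.01, of which 0 to 4 per comparison hold with an estimated correlation.

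The next comparison set serum-free against serum vesicles. These groups may also differ in medium, LIF and CHIR99021 dose, which the design cannot tell apart from serum. Serum-free vesicles carried more Ceacam1, a cell adhesion molecule (40.5 ± 13.8 against 3.59 ± 2.13 CPM, 10.8-fold, adjusted p = 1.33e-06), and more of the receptor Pla2r1 (6.27-fold), the ketosteroid enzyme Akr1c14 (5.37-fold) and Vim (4.61-fold). Hist1h1a, from a histone family of similar copies, rose 7.02-fold, and Fgf10 9.20-fold on 72 against 6 counts. They carried less of the junction protein Jam3 (16.97-fold lower), Cd80 (9.26-fold), the fibronectin receptor subunit Itga5 (7.58-fold) and Stra6 (7.47-fold). Usp9y was 15.3-fold lower, and as the cells were labelled female its reads may come from a related gene. Hnf4a rose 1.55-fold, Sparc 1.76-fold and Thbd 1.32-fold, and Axin2 fell 3.21-fold. Cdh1 (log2 fold change 0.03, adjusted p = 0.923), Gata6 (0.18, 0.447), Gata4 (0.26, 0.211), Lef1 (-1.61, 0.0558), Pou5f1 (-0.63, 0.403), Sox7 (0.35, 0.412) and Pdgfra (0.26, 0.250) missed the threshold.

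Cholesterol biosynthesis genes were higher without serum for 12 of 25 members and lower for 0, and 14 adjusted over the list alone (camera adjusted p = 0.00166, adjusted p = 0.359 with an estimated correlation). Fdps rose 1.77-fold and Idi1 1.63-fold. Proliferation genes were higher for 11 of 31 and lower for 1, also adjusted over the list alone (adjusted p = 0.00410, adjusted p = 0.396 with an estimated correlation), with Ccna2 at 1.73-fold, Rrm2 at 1.72-fold and Rrm1 at 1.58-fold. ER chaperones were higher for 8 of 18 and lower for 1, and 9 and 1 adjusted over the list alone (adjusted p = 0.0103, adjusted p = 0.359 with an estimated correlation, 0.0585 without serum vesicle replicate 2), with Calr at 1.88-fold, Xbp1 at 1.87-fold and Pdia3 at 1.53-fold.

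Mesenchymal transition genes were lower without serum for 5 of 12 and higher for 1, also adjusted over the list alone (adjusted p = 0.0272, adjusted p = 0.359 with an estimated correlation), including Ctgf (2.77-fold) and Itga5. Zeb1 had 2 counts against 37, a ratio of 0.0442 (95% counting interval 0.00516 to 0.171). This ended without serum vesicle replicate 3 (0.0752), without serum-free replicate 3 (0.0719), without a low-count filter (0.0939), after thinning (0.0938) and with the 2 groups alone (0.196). Fibroblast and feeder markers were lower for 3 of 7, and 4 adjusted over the list alone (adjusted p = 0.0405, adjusted p = 0.359 with an estimated correlation), with Tagln, a smooth muscle and fibroblast gene, 9.03-fold lower at 14 against 106 counts. That call ended without serum vesicle replicates 2 (0.0585) or 3 (0.130) or serum-free replicate 2 (0.152), on unstranded counts (0.0577) and after thinning (0.0938). Without serum-free replicate 3 the log2 fold change of Tagln was -4.21 (-3.17 with it), and on unstranded counts -2.39. The fibroblast collagens Col3a1 and Col5a1 fell 5.70- and 3.32-fold on 8 against 40 and 17 against 45 counts. Col3a1 lost its call without serum vesicle replicate 2 (log2 fold change -1.61, adjusted p = 0.232) or serum-free replicates 1 (0.0540) or 2 (0.120), and was at -3.14 without serum-free replicate 3. Col5a1 lost it without serum vesicle replicate 3 (-0.998, 0.278) or serum-free replicates 2 (0.0752) or 3 (0.163), after thinning (0.111) and with the 2 groups alone (0.138).

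Between the vesicle groups 2806 genes differed, 1482 higher and 1324 lower without serum, with 292 of the higher and 621 of the lower genes over 2-fold. The count was 1725 without serum vesicle replicate 3 and 1223 with the 2 groups fitted alone. The log2 fold changes of Jam3 and Stra6 were -5.03 and -4.11 without serum-free replicate 3 (-4.08 and -2.90 with it), and that of Jam3 was -4.83 after thinning. That of Fgf10 was 3.20, and it was 2.59 and 7.54 without serum vesicle replicates 1 and 2 and 2.56 without serum-free replicate 3. Axin2 missed the threshold without serum vesicle replicate 3 (adjusted p = 0.0896) and with the 2 groups alone (0.0506), and Hnf4a without serum vesicle replicate 3 (0.0680), without serum-free replicate 1 (0.0564) and with the 2 groups alone (0.0530). Thbd missed it without serum vesicle replicates 1 (0.0728) or 3 (0.183), without serum-free replicates 2 (0.165) or 3 (0.185), with passage as a covariate (0.0528), in the blocked fit (0.0523), after thinning (0.0571) and with the 2 groups alone (0.234). Pou5f1 passed without serum-free replicate 3 (log2 fold change -1.80, adjusted p = 0.0463), and Sox17, at 0.40 with an adjusted p of 0.0612, passed without serum vesicle replicate 2 (0.01004) and without a low-count filter (0.0107).

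Sorted and unsorted CHIR99021-vacuolated cells were then compared with each other. Sorted cells carried more immediate early transcripts, with Fosb at 728 against 6 counts (72.5-fold, adjusted p = 1.59e-05) and Jun at 84.3 ± 16.1 against 19.4 ± 2.18 CPM (4.34-fold, adjusted p = 5.98e-08). Mt-cyb rose 2.46-fold and Mt-nd4, on few reads, 4.44-fold. Gata6 rose 1.98-fold, Thbd fell 1.33-fold, and Pou5f1 (log2 fold change -0.06, adjusted p = 0.892), Cdh1 (0.33, 0.322), Vim (0.13, 0.725) and Axin2 (-0.03, 0.986) missed the threshold. So did Gata4 (0.15, 0.570), Sox17 (-0.27, 0.278), Sox7 (0.13, 0.812), Pdgfra (-0.22, 0.418), Hnf4a (-0.11, 0.812) and Sparc (-0.12, 0.588), and Lef1 had 0 counts in both groups. Among genes with a mean log2 CPM of at least 3 and no overlap between libraries, those that rose included Uqcrb (4.90-fold), Eif1b (4.62-fold) and the histone gene Hist2h2aa2 (4.89-fold), whose reads may be shared with similar copies. The non-coding RNAs RF01290, RF00319 and RF00563 fell 3.34-, 3.27- and 3.11-fold.

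Mitochondrially encoded genes were higher after the sort for 11 of 13 members, and 12 adjusted over the list alone (camera adjusted p = 2.66e-14, adjusted p = 0.166 with an estimated correlation). Immediate early genes were higher for 6 of 15 and lower for 0, and 7 adjusted over the list alone (adjusted p = 2.41e-05, adjusted p = 0.166 with an estimated correlation). These went with a mitochondrially encoded share of 6.76 to 8.91% against 2.88 to 4.08% and a depth of 4.48 M to 6.54 M against 3.02 M to 3.75 M counts. The 2 most abundant genes took 45.8 to 53.4% of counts in sorted against 44.3 to 52.2% in unsorted cells. Basement membrane genes were higher for 6 of 14, and 11 adjusted over the list alone (adjusted p = 1.83e-05, adjusted p = 0.208 with an estimated correlation), with Nid2 at 2.89-fold and Col4a1 at 1.96-fold. Lysosomal genes were higher for 6 of 35, and 10 adjusted over the list alone (adjusted p = 3.86e-04, adjusted p = 0.313 with an estimated correlation). Mesenchymal transition genes were higher for 4 of 12, and 5 adjusted over the list alone (adjusted p = 0.00927, adjusted p = 0.166 with an estimated correlation). Parietal endoderm genes were higher for 3 of 14 and lower for 1, and 7 and 1 adjusted over the list alone (adjusted p = 0.0143, adjusted p = 0.313 with an estimated correlation).

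The sort comparison called 1350 genes, 769 higher and 581 lower, with 289 over 2-fold. The count was 739, 690 and 876 without unsorted replicates 1, 2 and 3, 723 without sorted replicate 2 and 2576 with the 2 groups fitted alone. RF01290 missed the threshold without any 1 of the 6 libraries (adjusted p = 0.0674 to 0.167), with passage as a covariate (0.0553) and in the blocked fit (0.0519), and Thbd without any 1 of them (0.0792 to 0.134) and without a low-count filter (0.0640). RF00319 missed it without unsorted replicates 1 (0.0590) or 2 (0.0629) or sorted replicate 2 (0.0754), and RF00563 without unsorted replicate 1 (0.0569) or sorted replicate 2 (0.0662). Fosb had a log2 fold change of 10.37 without unsorted replicate 1 and 5.57 without unsorted replicate 3 (6.18 with both).

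The routes to vacuolation also differed, as unsorted cells with CHIR99021 and with BCS showed. With CHIR99021 the cells carried more Gata2 (15.9-fold, 11.3 ± 1.78 against 0.673 ± 0.541 CPM, adjusted p = 3.54e-08), Ckmt1 (11.8-fold) and the ephrin receptor Epha4 (6.46-fold). They carried less of the aldo-keto reductase Akr1b8 (13.6-fold lower), Dnmt3l (7.53-fold) and Igf2r (5.97-fold). Pou5f1 was 1.81-fold, Gata6 1.71-fold, Sparc 1.46-fold and Thbd 1.34-fold lower, Pdgfra 1.75-fold and Axin2 5.80-fold higher (33 against 6 counts), and Vim had a log2 fold change of -0.52 (adjusted p = 0.0689). Gata4 (-0.20, 0.422), Sox17 (0.08, 0.789), Sox7 (-0.65, 0.104), Hnf4a (-0.55, 0.0833) and Cdh1 (-0.19, 0.605) missed the threshold too, and Lef1 had 0 counts in both groups.

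Lysosomal genes were lower with CHIR99021 than with BCS for 22 of 35 members and higher for 1, and 23 and 1 adjusted over the list alone (camera adjusted p = 2.19e-15, adjusted p = 0.0260 with an estimated correlation), with Ctsb 3.05-fold and Ctsa 2.14-fold lower. Cholesterol genes were lower for 12 of 25 and higher for 0, and 16 adjusted over the list alone (adjusted p = 2.10e-09, adjusted p = 0.0260 with an estimated correlation), with Msmo1 2.17-fold lower. Mesenchymal transition genes were lower for 5 of 12, and 7 adjusted over the list alone (adjusted p = 8.18e-04, adjusted p = 0.0401 with an estimated correlation), with Ctgf 3.52-fold and Itga5 2.41-fold lower.

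Another 7 lists were lower with CHIR99021 than with BCS, with calls that an estimated correlation ended. Fatty acid synthesis genes were lower for 6 of 14 and higher for 1, and 9 and 1 adjusted over the list alone (adjusted p = 8.18e-04, adjusted p = 0.157 with an estimated correlation). Immediate early genes were lower for 5 of 15, and 6 adjusted over the list alone (adjusted p = 9.04e-04, adjusted p = 0.169 with an estimated correlation). Basement membrane genes were lower for 6 of 14 and higher for 1, and 7 and 1 adjusted over the list alone (adjusted p = 9.04e-04, adjusted p = 0.207 with an estimated correlation). Hypoxia and glycolysis genes were lower for 8 of 27 and higher for 1, and 10 and 1 adjusted over the list alone (adjusted p = 0.00155, adjusted p = 0.157 with an estimated correlation). Epithelial genes were lower for 9 of 31 and higher for 2, and 12 and 4 adjusted over the list alone (adjusted p = 0.00784, adjusted p = 0.159 with an estimated correlation). ER chaperones were lower for 4 of 18, and 5 adjusted over the list alone (adjusted p = 0.0172, adjusted p = 0.227 with an estimated correlation, 0.0519 without BCS-vacuolated replicate 2). Parietal endoderm genes were lower for 4 of 14 and higher for 1, and 8 and 1 adjusted over the list alone (adjusted p = 0.0210, adjusted p = 0.215 with an estimated correlation, 0.0851 without BCS-vacuolated replicate 2). Wnt targets were higher with CHIR99021 for 3 of 13 and lower for 1, and 4 and 1 adjusted over the list alone (adjusted p = 0.0263, adjusted p = 0.157 with an estimated correlation, 0.0646 without BCS-vacuolated replicate 2 and 0.0642 after thinning).

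This comparison held 1522 genes, 671 higher and 851 lower with CHIR99021, with 525 over 2-fold. The count was 863 and 815 without CHIR99021-vacuolated replicates 1 and 2, and 748 and 983 without BCS-vacuolated replicates 1 and 3. Igf2r missed the threshold without any of the 3 CHIR99021-vacuolated replicates (adjusted p = 0.0659, 0.0752 and 0.0540), without BCS-vacuolated replicates 1 (log2 fold change -1.95, 0.0945) or 3 (0.0504) and with the 2 groups alone (0.134). Axin2 missed it without any of the 3 CHIR99021-vacuolated replicates (0.0839, 0.0954 and 0.0812), without BCS-vacuolated replicates 1 (0.108) or 2 (log2 fold change 1.85, 0.118) and after thinning (1.95, 0.170), and stood at 3.43 without BCS-vacuolated replicate 3 against 2.54 with all. Thbd missed it without CHIR99021-vacuolated replicates 1 (0.1004), 2 (0.108) or 3 (0.0619) or BCS-vacuolated replicate 2 (0.129), and Vim passed without CHIR99021-vacuolated replicate 3 (log2 fold change -0.71, 0.0329) and, among the other settings, in 5 of them with an adjusted p from 0.0155 to 0.0488. Without BCS-vacuolated replicate 2 the log2 fold changes of Gata2 and Epha4 were 4.88 and 3.29 (3.99 and 2.69 with it).

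The last comparison set serum vesicles against unsorted CHIR99021-vacuolated cells. Tmprss2 rose 34.3-fold (260 ± 20.7 against 7.51 ± 1.42 CPM, adjusted p = 3.09e-17), Mir675 33.5-fold and Ypel5 28.1-fold, and Fgf10 fell from 708 to 6 counts (101-fold), Pdzd3 30.9-fold, Tfec 30.5-fold and Pou5f1 29.9-fold. Cdh1 rose 8.78-fold, Axin2 10.2-fold and Hnf4a 4.43-fold, and Lef1 had 53 counts against 0, at least 19.8-fold higher. Vim fell 11.1-fold, Thbd 9.17-fold, Gata6 3.52-fold, Sparc 2.52-fold, Sox17 2.03-fold, Gata4 1.78-fold and Sox7 1.65-fold, and Pdgfra had a log2 fold change of -0.06 (adjusted p = 0.769).

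Epithelial genes were higher in the vesicles for 23 of 31 and lower for 2, also adjusted over the list alone (camera adjusted p = 4.79e-07, adjusted p = 0.0185 with an estimated correlation), with Cldn7 at 37.2-fold and Ocln at 4.32-fold. Fluid transport genes were higher for 12 of 15 and lower for 2, also adjusted over the list alone (adjusted p = 1.92e-04, adjusted p = 0.0185 with an estimated correlation). Wnt targets were higher for 9 of 13 and lower for 2, and 9 and 3 adjusted over the list alone (adjusted p = 0.00829, adjusted p = 0.0678 with an estimated correlation). Lysosomal genes were higher for 25 of 35 and lower for 2, and 27 and 4 adjusted over the list alone (adjusted p = 7.53e-06, adjusted p = 0.127 with an estimated correlation), with Ctsb at 7.94-fold and Glb1 at 4.61-fold. Mitochondrially encoded genes were higher for 12 of 13, also adjusted over the list alone, beside a share of 7.91 to 9.31% against 2.88 to 4.08% of counts. Their camera adjusted p was 7.00e-05, and 0.332 with an estimated correlation. Proliferation genes were lower for 26 of 31 and higher for 2, also adjusted over the list alone (adjusted p = 6.12e-09, adjusted p = 0.0610 with an estimated correlation), with Ttk and Bub1 3.23- and 3.22-fold lower. ER chaperones were lower for 13 of 18 and higher for 2, and 13 and 3 adjusted over the list alone (adjusted p = 3.05e-04, adjusted p = 0.127 with an estimated correlation). ERK feedback targets were lower for 8 of 14 and higher for 1, also adjusted over the list alone (adjusted p = 0.0325, adjusted p = 0.127 with an estimated correlation, 0.0937 without serum vesicle replicate 2).

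This comparison called 6666 genes, 3489 higher and 3177 lower in the vesicles, with 3665 over 2-fold. Sox7 missed the threshold without any of the 3 CHIR99021-vacuolated replicates (adjusted p = 0.0681, 0.0631 and 0.0778) or serum vesicle replicate 2 (0.199), without a low-count filter (0.0514), with passage as a covariate (0.0696), after thinning (0.218) and with the 2 groups alone (0.0616). The log2 fold change of Fgf10 was -10.99 without serum vesicle replicate 2 and -6.04 without replicate 1 (-6.66 with both), and that of Tfec -5.58 without replicate 1 (-4.93 with it).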

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

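The test of depth for the first pattern below was chosen only after the result was seen, and the tests of its cell types were written before their markers were looked at, apart from the upper limit, which was added after.

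Serum-free vesicle replicate 2 held some transcripts of visceral endoderm and gut that no other library showed at that level, in genes with too few counts elsewhere to be compared. It had 346 counts of Apoa1, 252 of Afp, 219 of Apoa4, 118 of Apoc2 and 87 of Fgb, against at most 8 in any other library, including all controls. In all, 18 genes had at least 20 counts in that library and over 8 times the level of any other, Meltf (129 counts against at most 9) among them, and the summed level of Afp, Apoa1, Apoa4, Apob and Fgb was 118 CPM against 7.30 in the next. Of the fixed genes, Ttr had 3 counts over all 18 libraries. Of 14 genes seen first, 6 had at least 10 counts there and over 3 times the level of any other library. Among those that did not, Alb had 0 counts there and Fgg 1. Hnf4a stood at 64.3 CPM against 75.9 in serum-free replicate 1. Cubn (42.0 against 569 CPM) and Amn (3.64 against 96.5) were far lower there than in the highest BCS-vacuolated library.

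Greater depth was excluded, since after thinning all libraries to equal counts outside the 2 most abundant genes the summed level of Afp, Apoa1, Apoa4, Apob and Fgb was still 14.4 times the next highest. Liver-like or yolk-sac-like cells stayed open, as of 9 further genes of those tissues in the files 2, Apoh and Slc2a2, had at least 10 counts and over 3 times the level of any other library. That met the bound of 3 set beforehand against them, but the bound allowed for no spread (upper limit 5.50 of 10) and the other 7 genes had at most 8 counts there. Enterocyte-like cells also stayed open, with 5 of 10 further genes meeting that rule, under the 6 set beforehand, among them Fabp2 (58 counts against 0 elsewhere) and Muc13 (390 against at most 101). The summed level of Afp, Apoa1, Apoa4, Apob and Fgb before thinning was 2.37 to 7.30 CPM in serum vesicles. It was 2.07 and 0.699 in the other serum-free vesicles and at most 0.388 in all other libraries. Other vesicle libraries thus held these transcripts at a lower level, on at most 48 counts. A mixed or separately differentiated culture may account for the level in this single library, and the design has no group that can decide it.

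The share of counts on the other strand was 2.67% in the lowest unsorted CHIR99021-vacuolated library, above all normal libraries (at most 2.63%), while sorted libraries lay below them at 2.01 to 2.04%. It was flagged because that column was not part of any comparison, and it was not followed up.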

How the results depend on the processing

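The alternatives with unstranded counts, without the 2 most abundant genes and with thinning to equal counts outside those 2, and the tests made with them, were chosen only after the result was seen. Of 294 named-gene results, 294 kept direction and side of the threshold without those 2 genes, 292 with DESeq2 size factors and 290 with DESeq2, and 293 of 293 did on unstranded counts. With passage 288 of 294 were kept, with the replicate block 289, without a low-count filter 287, after thinning 270 of 283 and with the 2 groups alone 260 of 280. Leaving out each library in turn, 1662 of 1764 were kept, 75 lost the threshold, 7 gained it and 20 changed sign. Of 76 called lists, an estimated correlation kept 15, thinning 68, the 2 groups alone 69, no filter 73, unstranded counts and fry 74, and the block and passage 75, and none changed direction. Leaving out a library mostly lowered the number of calls and in some cases raised it, and the cause was not tested.

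Fitting only the 2 groups compared gave 1856 genes for CHIR99021-vacuolated against normal cells (876 in the full fit), 1223 for serum-free against serum vesicles (2806) and 2576 for sorted against unsorted cells (1350). With 1 library left out the counts ranged from 504 to 638 for CHIR99021-vacuolated, 1275 to 2606 for BCS-vacuolated and 1982 to 2471 for sorted against normal cells. They ranged from 6412 to 6916 for serum and 6074 to 6387 for serum-free vesicles against normal cells, 1725 to 3004 between vesicles, 690 to 954 for the sort, 748 to 1947 between CHIR99021 and BCS, and 6004 to 6598 for serum vesicles against vacuolated cells. The overlap of the 3 vacuolated groups ranged from 228 to 400. With replicate number as a block the counts were 832, 2281, 2860, 6889, 6555, 2568, 1232, 1451 and 6574 and the overlap 369. Replicate numbers gave no sign of pairing samples, as 45 pairs correlated at -0.230 to 0.104, 17 of them best with their own number. Some replicates of the same number also shared a passage. Normal and CHIR99021-vacuolated cells did at passages 37 and 51, with correlations of -0.00339 and 0.0264. The vesicle groups did at passages 32 and 35, with correlations of -0.107 and -0.0831.

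In all, 28 values changed sign, each of a gene that was not called and had a log2 fold change of at most 0.15 in size. After thinning, Hnf4a stood at -0.0234 in CHIR99021-vacuolated against normal and at 0.0639 in sorted against unsorted cells, Gata6 at -0.0443 in BCS-vacuolated and Sox7 at -0.0248 in serum vesicles against normal cells. Axin2 in sorted against unsorted cells was at 0.0117 with the block, 0.0474 with passage and 0.4845 after thinning. Cdh1 between the vesicle groups was at -9e-04 with those groups alone. With 1 library left out the ranges were -0.1235 to 0.3703 for Hnf4a in CHIR99021-vacuolated, -0.0558 to 0.284 for Sox17 in BCS-vacuolated, and in sorted against normal cells -0.1491 to 0.0685 for Sox17, -0.0153 to 0.2306 for Pdgfra and -0.0421 to 0.1029 for Hnf4a. They were -0.1417 to 0.3273 for Sox7 in serum vesicles against normal cells and -0.0817 to 0.1759 for Cdh1 between vesicles. In sorted against unsorted cells they were -0.1716 to 0.114 for Pou5f1, -0.3292 to 0.164 for Hnf4a and -0.3735 to 0.1431 for Axin2. For Sox17 between CHIR99021 and BCS the range was -0.0194 to 0.278, and for Pdgfra in serum vesicles against vacuolated cells -0.1831 to 0.0457.

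Some genes that were not called passed in other settings. In CHIR99021-vacuolated against normal cells these were Pdia6 with the block (adjusted p = 0.0499), DESeq2 size factors (0.0475), DESeq2 (0.0312), no filter (0.00946) and the 2 groups alone (1.90e-04), and Dnajb11 after thinning (0.0400), with DESeq2 size factors (0.0499), DESeq2 (0.0310), no filter (0.0297) and the 2 groups alone (8.13e-04). With those groups alone Sox7 (0.0410), Pdgfra (0.00595) and Sparc (0.0199) passed too. In BCS-vacuolated against normal cells Gata4 passed with the block (0.0433) and without BCS-vacuolated replicate 2 (0.0260). Pdgfra passed there with passage (0.0494), no filter (0.0240), the 2 groups alone (0.0316) and without BCS-vacuolated replicate 2 (0.0379), and Thbd with the 2 groups alone (0.0467). Gata6 passed in sorted against normal cells with those groups alone (0.0348), Pdgfra in serum vesicles without serum vesicle replicate 2 (0.0397), and Sparc in serum-free vesicles after thinning (0.0435), with DESeq2 (0.0300) and with the 2 groups alone (0.0488). Between CHIR99021 and BCS, Sox7 passed with those groups alone (0.0434) and Hnf4a without CHIR99021-vacuolated replicate 1 (0.0280).

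Afp, Ttr and Apoa1 had too few counts to be tested. In simulated data 40% of genes changed 1.5-fold were called, with the changed genes drawn from the more highly expressed ones. Whether depth, the number of replicates or their spread set this limit was not tested. DESeq2 gave no adjusted p for 225 genes in sorted against normal and 1340 in sorted against unsorted cells.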

Other observations

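The tests of Usp9y, the second factor and the response to the sort below, and the genes named here, were chosen only after the result was seen.

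The 3 vacuolated groups, 2 of them with the same CHIR99021 treatment, shared 391 genes that differed from normal cells in the same direction. Of these, 268 were higher and 123 lower. Both vesicle groups showed the same direction for 316 of them, while 20 were called in the opposite direction in a vesicle group. The lipoprotein receptor Vldlr had log2 fold changes of 6.46, 4.89 and 7.64 with CHIR99021, BCS and the sort, the actin regulator Eps8 of 3.81, 3.23 and 4.79, and Ndrg1 of 3.01, 3.72 and 3.93. Kcnip3 stood at -3.43, -3.35 and -3.54 and the gut peptide gene Pyy at -3.19, -2.40 and -2.12. Higher in all 3 were 8 of 27 hypoxia and glycolysis genes, 5 of 31 epithelial genes and 4 of 35 lysosomal genes. Without normal replicate 2 the overlap was 228, without normal replicate 3 it was 251, and without CHIR99021-vacuolated replicate 1 it was 260.

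These groups were compared with the same 3 normal libraries, which alone makes their changes alike. Independent lists of those sizes would share 8.30 higher and 3.94 lower genes, but 2 of the 3 groups had the same treatment. In 20 simulations with shared controls and no change the overlap was at most 0, which does not show what shared controls add to real changes. The log2 fold changes of the vesicle groups correlated at 0.884 (simulated 0.512) with a covariance of 1.59 (0.0472), and 2757 genes were higher and 2455 lower in both (1098 and 910 if independent). CHIR99021-vacuolated and sorted cells correlated at 0.686 (0.538) with a covariance of 0.222 (0.0470), sharing 417 higher and 229 lower genes (74.1 and 41.4). CHIR99021- and BCS-vacuolated cells correlated at 0.491 (0.526) with a covariance of 0.155 (0.0471), sharing 318 and 153 (57.8 and 34.2), and BCS-vacuolated and sorted cells at 0.551 (0.543) with a covariance of 0.208 (0.0471), sharing 692 and 523 (185 and 126). Vacuolated groups and vesicle groups correlated at 0.400 to 0.596 (0.509 to 0.540) with covariances of 0.294 to 0.500 (0.0469 to 0.0472). The correlation of CHIR99021- with BCS-vacuolated cells lay below its simulated value. So did those of vacuolated with vesicle groups, apart from sorted cells with serum vesicles (0.596 against 0.529). Those correlations alone thus show nothing beyond shared controls. Since 3 controls cannot be split with at least 2 on each side, part of the excess in covariances and shared genes may come from the shared controls. The overlap without normal replicate 2 was 228.

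Some lists written beforehand were called in no comparison. Among primitive endoderm factors, 3 of 13 were higher and 8 lower in serum vesicles against normal cells, and 3 and 8 adjusted over the list alone (camera adjusted p = 0.102). For V-ATPase genes, which acidify vacuoles, 0 of 17 were higher or lower in CHIR99021-vacuolated cells, also adjusted over the list alone (adjusted p = 0.375), and in BCS-vacuolated cells 2 of 17 were higher and 1 adjusted over the list alone (adjusted p = 0.985). Anterior visceral endoderm genes were lower for 4 of 6 and higher for 1 in serum-free vesicles against normal cells, also adjusted over the list alone (adjusted p = 0.0954). In the same comparison LIF STAT3 targets were lower for 5 of 14 and higher for 2 (adjusted p = 0.140), trophoblast markers higher for 2 of 4 and lower for 2 (0.630) and blood and immune markers lower for 3 of 4 (0.0938), with the same counts adjusted over the list alone. BMP SMAD targets there were higher for 5 of 11 and lower for 5, also adjusted over the list alone, with a median of -0.52 but a mean of 1.41 and an upward test (adjusted p = 0.792). Of 2 tested mesoderm and streak markers, 1 was higher in that comparison.

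Immediate early and mitochondrially encoded genes were higher in sorted than in unsorted CHIR99021-vacuolated cells. Greater depth was excluded for both, as camera's adjusted p after thinning was 4.27e-05 and 5.73e-16 at the preset correlation, though with an estimated one neither list passed before thinning (0.166 each). Whether enrichment of vacuolated cells by the sort was the whole cause could not be decided. The factor for it from 873 genes was 0.908, which predicts a smaller change from normal cells than unsorted cells showed. Lists picked as higher in sorted cells were bound to exceed that prediction. They did so by a median log2 of 0.650 (interval 0.476 to 0.997) and 1.16 (1.05 to 1.29). That first factor may be too low, as its genes were chosen on the unsorted libraries. A second factor, from 2955 genes called in sorted cells, left 0.394 (0.095 to 2.10) and 1.06 (0.795 to 1.20). These intervals cover the spread between genes of a list, which may change together, and not the spread between libraries. A response of the cells to the sort stayed open, as 2 unsorted vesicle libraries lay above the lowest sorted library in mean log2 CPM of immediate early genes, and the sort cannot be told apart from the group itself.

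Usp9y, a Y-linked gene, had 3674 counts in normal cells that were labelled female, 1594 in serum vesicles and 119 in serum-free vesicles. In serum-free vesicles it was lower than in serum vesicles by a log2 fold change of -3.93 (adjusted p = 3.96e-05). A fixed share of reads of its X-linked relative Usp9x was excluded, as the ratio of Usp9y to Usp9x differed 71.7-fold between groups. Loss of a Y chromosome in serum-free vesicles stayed open. The lower of the log2 fold changes of Eif2s3y and Kdm5d was 0.33, but their reads may come from X-linked relatives, and with Sry at most 1 count and Ddx3y at most 16 in any library the test was void. Reads of other related genes or a variant of the strain were not tested.

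With 3 libraries in each group only 10 splits of the 6 libraries exist for each comparison, too few for a share under 0.05, and in each comparison 1 of 10, the real one, called as many genes. Each other split mixed libraries of both groups on each side, so real differences between groups would raise the spread within a side. Few calls in such splits were thus likely in advance and do not show a chance level. The highest other split of the vesicle groups called 248 genes against 2806. By edgeR every other comparison had 0 in its highest other split, where 362 (CHIR99021-vacuolated against normal), 1098 (BCS-vacuolated), 573 (sorted), 1116 (serum vesicles) and 900 (serum-free vesicles) genes had an unadjusted p under 0.05. That number was 743 for the sort, 1044 for CHIR99021 against BCS and 1282 for serum vesicles against vacuolated cells. The real counts were 876, 2383, 2974, 6950, 6633, 1350, 1522 and 6666.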
